A study of Mus musculus with 4 samples.

How the data were processed

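MicroRNAs (miRNAs) were measured on 4 one-colour arrays in MC3T3-E1 cells, a clonal osteoblastic line from mouse calvaria. Each array held total RNA from cells in proliferation medium that overexpressed GFP, Wnt4, Wnt3a or Wnt5a from an adenovirus vector. Per the labels' protocols, RNA was labelled with the Hy5 dye by a kit made for LNA miRNA arrays, and per the file headers the arrays were scanned at 635 nm. Per the file headers each array was read at 3 gains, related by lines whose slopes were 0.303, 0.271, 0.304 and 0.303 between the first and second gain on the GFP, Wnt4, Wnt3a and Wnt5a arrays. The gains themselves are not given, so equal settings on all arrays are not known, and values without normalization between arrays assume them. The scanner model is not given in the sources used here.

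The deposited scanner files hold a raw median intensity for each of 3200 spots per array, and a background median for each spot. There were 1900 miRNA probes with 1 spot each, of which 12 carried the names of several miRNAs, besides 896 blank spots, 174 spots without probe and control probes. The 2 probes miR-3474 and miR-7659-5p were marked as not good on the GFP array and were left out, which left 1898. The deposited table of processed values, also an intensity, lists a value only for some miRNAs on each array. Its scale was worked out by setting each column against that array's scanner values: every listed intensity of the authors' table equalled the spot median minus the blank mean, times 1 factor per array, to within 0.204 units. Its median was 25 on every array.

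The background column could not serve as a local background, because it followed the spot's own signal: the Pearson correlation of the log2 values lay between 0.942 and 0.985. The design fixed before the data were examined had foreseen normexp on foreground and background. Normexp was therefore run on the spot medians alone, with an offset of 50, over all spots, and the background column became an added alternative. Control spots were then left out and the 1898 probes were quantile-normalized over the 4 arrays, with limma 3.58.1 in R 4.3.3. Later steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for plots.

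A miRNA counted as detected on an array when its spot median lay above the mean plus 2 SD of the middle 95% of that array's blank spots. Log2 differences were taken between 2 arrays for miRNAs detected on both, and miRNAs at least 2-fold higher or lower were counted. For a miRNA detected on only 1 of 2 arrays, the brighter value was set against the detection limit or the dim value, whichever was higher, which gives a bound. The number of arrays limits the precision. No p-value was computed, since there was 1 array per group. A spot-noise standard error was estimated from control probes with replicate spots on each array. It covers variation between spots within an array, and neither hybridisation nor cultures.

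The miRNAs named in the text followed a rule fixed before the data were examined. It took up to 10 miRNAs each way per comparison with GFP, at least 2-fold different and above the median level of miRNAs detected on all 4 arrays. To these it added the 3 brightest detected on only 1 array each way, the 5 brightest on the GFP array, the miR-140 locus, and for each list up to 4 members with the highest level and the member with the largest difference. Comparisons between Wnt arrays added up to 5 each way. miRNAs between 1.5-fold and 2-fold were named after their values were seen. In all, 25 lists of miRNAs were fixed in advance: families, clusters, pathways and markers of other cell types. Every arm of a listed miRNA, 5p or 3p, counted as a member. A list's median was placed among 10000 random lists of the same size matched on level, for lists with at least 3 detected members, as a description of these arrays. Random lists draw miRNAs independently, whereas members of a family or cluster can share sequence or a precursor. A percentile therefore does not measure how unlikely a list is.

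Genes that host or neighbour a miRNA were looked up by name in the RefSeq gene table of assembly GRCm38.p6, where 1884 of the 1898 probe names had a match. The files name no genome build, so no coordinates are given.

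The counting was tested on simulated data for the comparison of Wnt3a with GFP over 1898 probes. Of 67 miRNAs simulated 2-fold changed, 6 were counted, with a median log2 difference of 0.59. Of 66 simulated 4-fold changed, 40 were counted, with a median of 1.19. None of 391 detected unchanged miRNAs was counted. The offset and the dim signal thus shrank true folds. In 100 simulations of unchanged arrays against a simulated GFP array, 0 miRNAs reached 2-fold. Apart from the changed miRNAs, all simulated arrays had the same true levels, with each array's own blank mean and spot noise. Variation between hybridisations or cultures was left out, so these counts are no rate of false calls between real arrays.

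In all, 12 alternatives fixed in advance changed the background correction, the normalization between arrays, the source of the values, the filter on dim probes or the size rule. Another 5 were chosen after seeing the data: the background column, scaling on the 5 bright control probes, the deposited table rescaled on miRNAs listed on all 4 arrays, and detection limits from spots without probe or from negative control probes. The negative control probes were 80 spots of 9 control probes. These were Negative Control 1, 2 and 3 and several S-Probes, whose targets are not given in the sources used here.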

Results

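The series asks which miRNAs take part in the crosstalk of Wnt and TGF-beta signalling in osteoblastic cells. miRNA levels were measured in mouse MC3T3-E1 cells that overexpressed GFP, as the control, or 1 of 3 secreted Wnt ligands, on 1 array per group. Wnt3a is the classical activator of beta-catenin signalling, Wnt5a is best known for beta-catenin-independent signalling, and Wnt4 has been linked to both. There were no replicates, so every difference below is between 2 arrays, has no replicate check and carries only the spot-noise standard error (SE).

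Of 1898 miRNA probes, 616 were detected on the GFP array, 547 on the Wnt4 array, 1063 on the Wnt3a array and 502 on the Wnt5a array. The detection limits were 104, 86.9, 81.7 and 111 intensity units in the same order, and 482 miRNAs were detected on all 4 arrays. The counts depended on the limit. They were 425, 389, 623 and 383 with the limit at 5 SD, fixed in advance. With 2 limits chosen after seeing the data they were 664, 573, 971 and 575 with the limit from spots without probe, and 572, 542, 610 and 523 with that from negative control probes. The 5 brightest miRNAs on the GFP array were miR-3968, miR-6366, miR-125b-5p, miR-2137 and miR-1902. Levels on each Wnt array correlated with those on the GFP array across miRNAs, which are not independent replicates, with Pearson's r of 0.996 for Wnt4, 0.982 for Wnt3a and 0.997 for Wnt5a. The 5 bright control probes differed from their GFP-array level by a mean log2 of -0.16, -0.08 and -0.10 on the Wnt4, Wnt3a and Wnt5a arrays.

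Wnt3a was compared with GFP to find miRNAs that respond to it. Both arms of miR-140, a cartilage-associated miRNA whose gene lies within Wwp2, were the lowest on the Wnt3a array relative to GFP. miR-140-3p was 6.68-fold lower, with a log2 difference of -2.74 (SE 0.12), and miR-140-5p 4.54-fold lower, at -2.18 (SE 0.12). Their signals were 7049 and 2379 units on the GFP array against 1135 and 535 on the Wnt3a array. On the Wnt4 and Wnt5a arrays miR-140-3p differed from GFP by -0.26 and -0.35, and miR-140-5p by 0.07 and -0.09. The miR-140 locus was recalled as the focus of the study's paper, so its choice is not independent evidence of its direction.

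Among 611 miRNAs detected on both arrays, 3 were at least 2-fold higher and 6 at least 2-fold lower with Wnt3a. The other lower ones were miR-146b-5p, of a family linked to NF-kappaB signalling, at -1.87 (SE 0.11), and 3 products of the X-linked cluster of miR-322 and miR-503. Of these, miR-503-5p was 2.36-fold, miR-322-5p 2.11-fold and miR-322-3p 2.07-fold lower. None of these 3 was 2-fold lower under plain subtraction or in the deposited table, where the median of all miRNAs was 1.02 and 1.47. All 3 were 2-fold lower in the deposited table rescaled on miRNAs listed on all 4 arrays. With scaling on the bright control probes 4 miRNAs in place of 6 were lower, and both miR-322 arms were under 2-fold. Without background correction miR-322-3p was under 2-fold as well. The signal of miR-146b-5p on the Wnt3a array, 86.3 units, was near the limit of 81.7, and the miRNA was no longer counted with the limits at 5 SD or from negative control probes, nor with the background column, where it was at -0.29. Over the alternatives that give it a value, its difference ran from -4.13 to -0.29. The higher ones were miR-7036a-5p, at 1.22 (SE 0.12), miR-711, whose gene overlaps Col7a1, at 1.18 (SE 0.13), and miR-21a-5p at 1.08 (SE 0.13). miR-21a-5p, an abundant miRNA often raised in proliferating cells, gave 6669 units on the GFP array and 12510 on the Wnt3a array. It was under 2-fold when scaled to the median, to the upper quartile or on the bright control probes, in the rescaled deposited table and, at 0.91, without normalization between arrays. miR-711 was under 2-fold in the rescaled deposited table, at 0.97. With the background column subtracted, which follows the spot's own signal, the direction turned for miR-503-5p, miR-322-3p and all 3 higher miRNAs, and in the deposited table for miR-322-5p.

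Another 8 miRNAs were between 1.5-fold and 2-fold lower with Wnt3a. They were miR-708-5p at -0.97, miR-351-5p of the same X-linked cluster at -0.80, miR-204-5p, a reported regulator of Runx2, at -0.74, miR-30a-5p and miR-30d-5p at -0.66, miR-30c-5p at -0.62, and miR-100-5p and miR-196a-5p at -0.59. All of these except miR-204-5p were above 0 in the deposited table, and miR-30a-5p, miR-30c-5p, miR-30d-5p and miR-100-5p also under plain subtraction. However, 98.4% of miRNAs listed on both arrays were above 0 in that table. The median of all miRNAs was 1.47 there and 1.02 under plain subtraction. Rescaled on miRNAs listed on all 4 arrays, the table put miR-708-5p, miR-351-5p, miR-196a-5p and miR-204-5p at least 2-fold lower. The miR-30 members and miR-100-5p were under 2-fold there. With the background column miR-204-5p, miR-351-5p and miR-30d-5p were above 0. Another 6 were between 1.5-fold and 2-fold higher. They were miR-6913-5p at 0.93, miR-31-5p at 0.79, miR-6769b-5p and miR-7047-5p at 0.77, miR-6546-3p at 0.76 and miR-6937-5p at 0.73. Of these, miR-6913-5p was below 0 with the background column and at least 2-fold higher in 6 settings, such as normexp with an offset of 16.

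**Figure D1:**
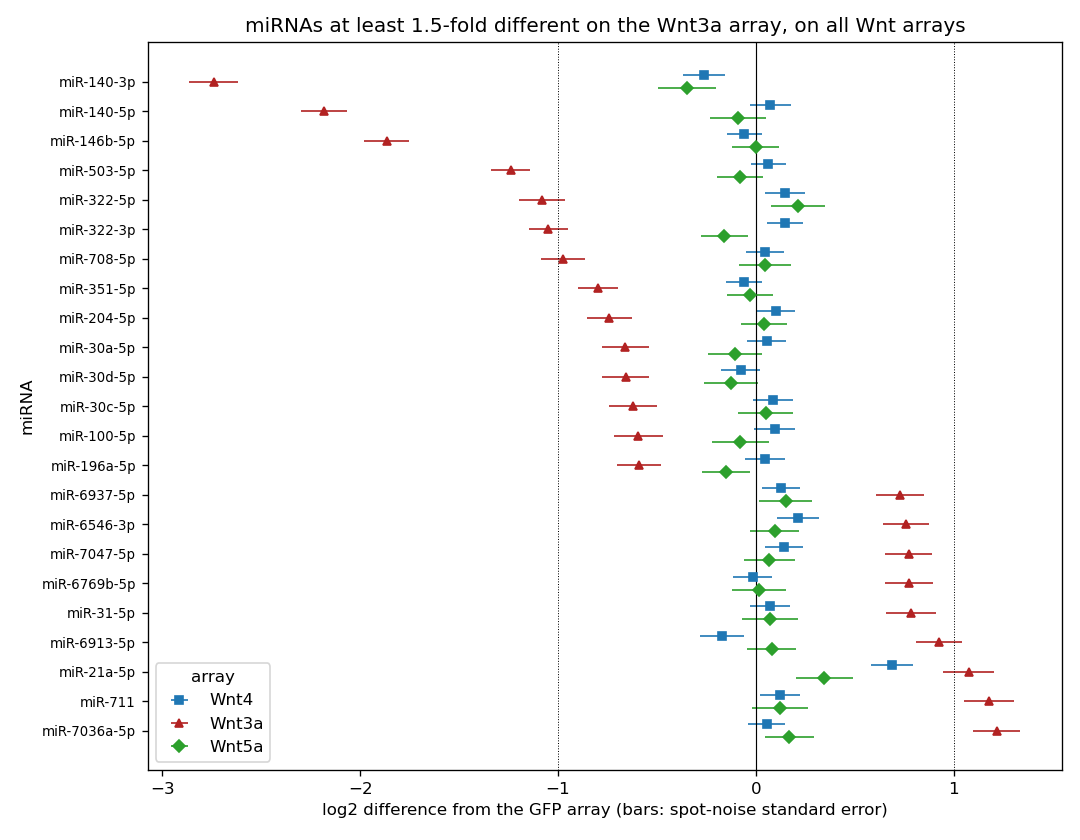
Log2 differences from the GFP array, on the x axis, of the 23 miRNAs at least 1.5-fold different on the Wnt3a array, each on the y axis, with squares for Wnt4, triangles for Wnt3a and diamonds for Wnt5a, and bars of 1 spot-noise standard error. miR-140-3p lies at -2.74 on the Wnt3a array and at -0.26 and -0.35 on the Wnt4 and Wnt5a arrays, and miR-21a-5p is above 0 on all 3 Wnt arrays. Without normalization between arrays, the difference of miR-21a-5p on the Wnt4 array was 0.00.

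Among lists with at least 3 detected members, which leaves out the miR-140 locus at a median of -2.46, the X-linked cluster of miR-322 and miR-503 had the lowest median with Wnt3a. All of its 8 detected members were below 0, with a median of -0.67, lower than all 10000 matched random lists. The miR-30 family, with reported Runx2 and Smad1 targets, had 7 of 7 members below 0 and a median of -0.48, at percentile 0.045. The members counted include the 3p arms miR-30a-3p at -0.31 and miR-30e-3p at -0.46. In the miR-15/16 family, which includes both arms of miR-322, 6 of 7 members were below 0 and the median was -0.43, at percentile 0.080. miR-15b-5p was at -0.50 and miR-15a-5p at -0.41, while miR-16-5p was at 0.00. Of 12 let-7 members, 10 were below 0, among them let-7d-5p at -0.44, with a median of -0.20 at percentile 2.16. The 41 detected osteoblast-regulating miRNAs had a median of -0.13, at percentile 0.115, with 27 below 0 and 14 above 0, and -0.04 when scaled on the bright control probes. They include miR-30, miR-204, miR-322 and miR-196a members already named, and also miR-2861 at 0.46 and miR-3960 at 0.44. The miR-17-92 clusters, associated with proliferation, had 11 of 16 members above 0 and a median of 0.15, at percentile 99.1, with miR-20a-5p at 0.39 and miR-17-5p at 0.23. These percentiles do not allow for members that share sequence or a precursor.

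The direction of these 6 list medians was kept under each scaling of the scanner values between arrays. It turned for let-7, miR-30, miR-15/16 and the osteoblast-regulating list under the deposited table, where the median of all miRNAs shifted by 1.47, and under plain subtraction, where it shifted by 1.02. With the background column it turned for let-7, the osteoblast-regulating list and the X-linked cluster, and the latter was at 0.29 under the deposited table.

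TGF-beta-responsive miRNAs had a median of 0.01 with Wnt3a over 16 members, at percentile 55.6, and Wnt-pathway-linked miRNAs one of -0.01 over 18, at percentile 27.4, and both changed sign between scalings. The cluster of miR-143 and miR-145a, induced by TGF-beta in several cell types, was at 0.17 over 4 members, with miR-143-3p at 0.49. The miR-29 family, which targets collagens, had a median of -0.31 over 3 members, which turned under the deposited table, plain subtraction and the background column. The clusters of miR-23, miR-27 and miR-24 were at 0.11, but at -0.14 when scaled to the median, and the cluster of miR-199 and miR-214 was at -0.03, but at 0.01 when scaled on the bright control probes. The miR-34 family was at 0.02, the Dlk1-Dio3 cluster at 0.01, below 0 under 3 of the scalings, and the Sfmbt2 cluster at 0.05, below 0 with the background column. All of these were within the middle 95% of random lists. The miR-181 family and the cluster of miR-182, miR-183 and miR-96 had under 3 members detected on both arrays, with medians of 0.08 and -0.12, the latter above 0 under the deposited table. Among markers of other cell types, the liver marker miR-122 was detected on no array. The highest signals on the GFP array, with a limit of 104, were 105 for the miR-200 family, 109 for endothelial, 134 for muscle, 313 for neural, 332 for pluripotency and 404 for blood cell miRNAs. On the Wnt3a array the last 3 were 331, 329 and 406. These are the brightest members only. On the GFP array the medians of the neural, pluripotency and blood cell lists were 93.0, 91.3 and 94.4, under the limit. There 4 of 19, 7 of 28 and 5 of 14 probes were detected, against 12, 12 and 7 on the Wnt3a array. Blood cell, neural and pluripotency lists had medians of -0.04, -0.08 and -0.10 with Wnt3a, within the middle 95% of random lists, and all were above 0 when scaled on the bright control probes.

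Of the miRNAs detected on only 1 of these arrays, 452 were detected with Wnt3a and 5 with GFP, and none was at least 2-fold different as a bound. The offset enters these bounds and shrinks the folds of dim signals, and no bound reached 2-fold in any comparison of 2 arrays. The lack of 2-fold bounds is therefore no evidence that the differences were small. The brightest with Wnt3a alone was miR-155-5p, an immune and NF-kappaB-linked miRNA, at least 1.44-fold higher, and the next were miR-3475-5p and miR-135a-2-3p, at least 1.20-fold and 1.15-fold higher. The signal of miR-155-5p was 135 units on the Wnt3a array, with a blank mean of 72.8. On the GFP array it was 96.8 units, with a blank mean of 90.8 and a limit of 104. Instead of 457 in all, 345 miRNAs were detected on only 1 of these arrays with the limit from spots without probe, 200 with that at 5 SD and 106 with that from negative control probes.

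**Figure D2:**
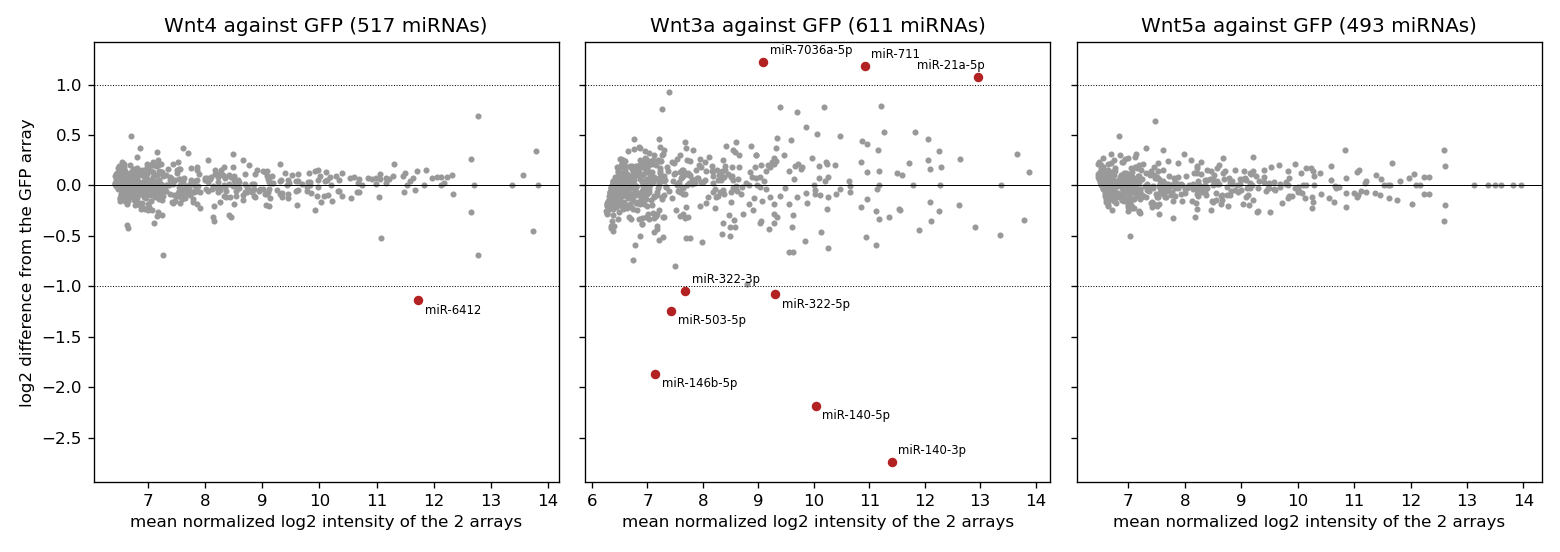
Log2 difference from the GFP array, on the y axis, against the mean normalized log2 intensity of both arrays, on the x axis, for miRNAs detected on both arrays, with 1 panel per Wnt gene and those at least 2-fold different in red. The Wnt3a panel holds 9 red points among 611, the Wnt4 panel 1 among 517 and the Wnt5a panel 0 among 493.

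With Wnt4, 1 miRNA of 517 detected on both arrays was at least 2-fold lower than with GFP and 0 were higher. miR-6412 was 2.20-fold lower, at -1.14 (SE 0.10), with 5631 units on the GFP array and 2042 on the Wnt4 array. At 1.5-fold, miR-5100 and miR-1983 were lower as well, both at -0.69, and the gene of miR-1983 overlaps that of a transfer RNA. Over the alternatives, miR-5100 ran from -3.67 to -0.68 and miR-1983 from -1.64 to -0.12. They were at least 2-fold lower in 2 and 3 settings. miR-21a-5p was at 0.69, but its signals were 6669 and 6673 units, and its difference was 0.00 without normalization between arrays and -0.01 in the deposited table. No list with at least 3 detected members lay outside the middle 95% of random lists. The X-linked cluster of miR-322 and miR-503 had a median of 0.11 at percentile 97.0, the miR-30 family 0.05 and the osteoblast-regulating list 0.03, and all of these were below 0 without normalization between arrays, where the median of all miRNAs was -0.17. There were 30 miRNAs detected with Wnt4 alone and 99 with GFP alone. Of those, miR-3544-3p was at least 1.45-fold higher with Wnt4, and miR-7044-3p at least 1.18-fold higher with GFP.

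With Wnt5a, 0 of 493 miRNAs detected on both arrays were at least 2-fold different from GFP, and 1 passed 1.5-fold. That was miR-5129-5p, whose gene lies in Zeb2, at 0.64 (SE 0.12), but at -0.28 under plain subtraction, where the median of all miRNAs was -1.14. The SD of the log2 differences was 0.13, against 0.14 with Wnt4 and 0.30 with Wnt3a. The osteoblast-regulating list had a median of -0.06, at percentile 0.810, and the Dlk1-Dio3 cluster one of 0.10, at percentile 97.6. The former was at 0.00 without normalization between arrays and at 0.11 with scaling on the bright control probes, where the median of all miRNAs was 0.13. The latter was below 0 under plain subtraction, in the deposited table, where the median of all miRNAs was -0.59, and without a filter on dim probes. There were 9 miRNAs detected with Wnt5a alone and 123 with GFP alone. miR-654-5p of the Dlk1-Dio3 cluster was at least 1.59-fold higher with Wnt5a, at 151 units against 84.4, and miR-6364 was at least 1.15-fold higher with GFP.

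The Wnt arrays were also compared with each other, which leaves out the shared GFP array. Each Wnt array is the same 1 as in its comparison with GFP. A miRNA that recurs here is therefore no separate check of that array. Relative to Wnt5a, Wnt3a had 2 miRNAs at least 2-fold higher and 6 lower, and relative to Wnt4 3 higher and 7 lower. miR-140-3p was at -2.39 and -2.48 in these comparisons, and miR-140-5p, miR-146b-5p, miR-322-5p, miR-503-5p and miR-708-5p were among the lower ones in both. miR-711 was at 1.06 in both and miR-7036a-5p at 1.05 and 1.16. Against Wnt5a, the 2 higher ones were under 2-fold when scaled to the median, scaled to the upper quartile or with cyclic loess. Against Wnt4, 4 miRNAs in place of 7 were lower without normalization between arrays. Between Wnt5a and Wnt4, 1 miRNA differed 2-fold, miR-6412, which was higher with Wnt5a by a log2 difference of 1.22. No miRNA was at least 2-fold from GFP in the same direction with all 3 ligands, and the only one shared by 2 ligands at 1.5-fold was miR-21a-5p. With Wnt4 its difference was 0.00 without normalization between arrays and -0.01 in the deposited table. Both of its comparisons share the GFP array.

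Across 482 miRNAs detected on all arrays, which are not independent replicates, the log2 differences from GFP correlated with Pearson's r of 0.24 for Wnt4 and Wnt3a, 0.46 for Wnt4 and Wnt5a and 0.36 for Wnt3a and Wnt5a. Spearman's rho was 0.28, 0.52 and 0.43. Simulated unchanged arrays with spot noise only, against a shared simulated GFP array, gave r of 0.46, 0.39 and 0.36. The covariances were 0.0116, 0.00886 and 0.0157, against simulated covariances of 0.00527, 0.00515 and 0.00522. The controls were a single array that could not be split, so part of any excess may come from it.

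The authors' deposited table gave another picture of Wnt3a. In it, 528 of 632 miRNAs listed on both arrays were at least 2-fold higher with Wnt3a than with GFP and 3 were lower, with a median ratio of 2.77. The 3 lower ones were miR-140-3p, miR-140-5p and miR-146b-5p, of which miR-140-3p was 2.85-fold lower in that table. There, 2 of 536 miRNAs were higher and 14 lower with Wnt4, and 0 of 506 higher and 63 lower with Wnt5a. The median log2 ratio was -0.28 with Wnt4 and -0.59 with Wnt5a. On the log2 scale the table's factor for the Wnt5a array differed from that for the GFP array by -0.51. Rescaled on miRNAs listed on all 4 arrays, the table put 3 higher and 6 lower with Wnt4, and 2 higher and 7 lower with Wnt5a.

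**Figure D3:**
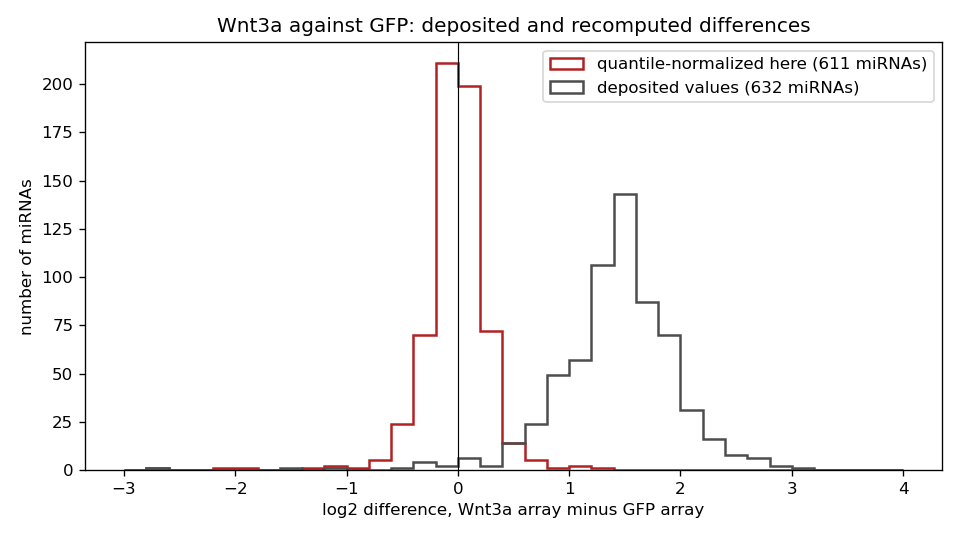
Number of miRNAs, on the y axis, by log2 difference between the Wnt3a and GFP arrays, on the x axis in bins of 0.2, for the deposited values (632 miRNAs) and the values normalized here (611 miRNAs). The deposited differences centre on a median of 1.47 and the others on 0.00.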

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

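All tests of explanations in this part except that of the array blocks were chosen after the result was seen. Control probes of the manufacturer with 1 spot each belong to no comparison above, and what they bind is not given in the sources used here. Scaled on the bright control probes, S-Probe1007 was above its GFP-array level by a log2 difference of 0.29 on the Wnt3a array and 0.32 on the Wnt5a array. S-Probe1016 was above it by 0.32 on the Wnt3a array. These 3 of 21 differences, of 7 probes on 3 arrays, lay outside the 95% range of spot noise, which leaves out variation between arrays.

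The deposited table, which the comparisons above do not use for their counts, put 528 miRNAs at least 2-fold higher on the Wnt3a array than on the GFP array. Had they been about 2-fold higher, their log2 differences in signal over blank, free of the array factors and scaled on the bright control probes, would lie near 1, but the median was 0.42 and the upper quartile 0.69, and 38 of the 528 were still 2-fold higher. The authors' table is the spot median over blank times 1 factor per array, which brings the median of each array's own listed miRNAs to 25. As 1113 miRNAs were listed on the Wnt3a array and 638 on the GFP array, the factors differed by 1.20 on the log2 scale, most of the median of 1.47. Scaling over unlike sets of miRNAs is thus a candidate cause of most of this pattern.

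On the Wnt3a array 1063 miRNAs were detected against 616 on the GFP array, an excess of 447. The blank spots may have read low relative to spots that carry a probe: negative control probes lay 4.52 units above the blank mean on the Wnt3a array and -3.18 units from it on the GFP array. These are means over all 80 spots of 9 control probes, which differed from each other. Negative Control 1, 2 and 3 averaged 93.1, 71.5 and 78.5 units on the Wnt3a array, with a blank mean of 72.8. On the GFP array they averaged 103, 87.2 and 89.7 units, with a blank mean of 90.8. With the limit from negative control probes the excess was 38, but it was 198 with the limit at 5 SD and 307 with that from spots without probe, so this account rests on the negative control probes alone. The 452 miRNAs detected only with Wnt3a lay higher over negative control probes than on the GFP array by a median of 1.63 units, against 8.93 units between blank mean and limit. They lie near the floor, so a presence of some of them with Wnt3a alone cannot be told apart from this shift.

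The 6 miRNAs at least 2-fold lower with Wnt3a lay in 5 blocks of the array. A defect over most of a block would have lowered other miRNAs of those blocks, but the lowest of their block medians was -0.0694. Over all 32 blocks the medians ran from -0.17 to 0.14. A defect of a few spots would not move a block median, so this test cannot decide on one. Both arms of miR-140 lay in the same block, whose median was 0.0 over 27 miRNAs. A response to Wnt3a remains open, and so do a defect of a few spots and variation between cultures unrelated to Wnt3a. With 1 array per group these cannot be told apart.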

How the results depend on the processing

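The alternatives with the background column, the bright control probes, the rescaled deposited table and the limits from spots without probe or negative control probes were chosen after seeing the data. miR-140-3p and miR-140-5p were at least 2-fold lower with Wnt3a than with GFP in all 16 settings that give them a value, from -2.94 to -1.51 and from -2.50 to -1.11, and miR-6412 was so with Wnt4, from -1.58 to -1.13. Settings that change only the filter or the detection limit reuse the main values, so they are no separate check of these differences. Of 17 alternatives, 12 shared at least 5 of the 6 miRNAs counted as lower with Wnt3a. Those with the 1.5-fold rule or without a filter on dim probes keep all 6 by construction. Plain subtraction, the deposited table and the 3-fold rule shared 3, the background column 2 and scaling on the bright control probes 4. Of 997 list medians under the alternatives 225 had the opposite sign, many of them near 0. Of 4429 values of single miRNAs, which include repeats of the main value where only detection changed, 674 had it. Among these, 18 medians belonged to lists outside the middle 95% of random lists and 6 values to miRNAs at least 2-fold different, and these are given here. Signal over background set the limits: most miRNAs were near the blank spots, where small shifts of the background decide what is detected. No paired analysis was possible because each group has 1 array. Each alternative fixed in advance was run.

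The counts are given by direction under plain subtraction of the blank mean, with the authors' processed values, with those values rescaled on miRNAs listed on all 4 arrays, with the background column subtracted before normexp, with 1.5-fold and with 3-fold in place of 2-fold, in this order. Wnt4 against GFP: miRNAs at least 2-fold higher numbered 1, 2, 3, 29, 1 and 0. Wnt4 against GFP: miRNAs at least 2-fold lower numbered 5, 14, 6, 36, 3 and 0. Wnt3a against GFP: miRNAs at least 2-fold higher numbered 317, 528, 18, 15, 9 and 0. Wnt3a against GFP: miRNAs at least 2-fold lower numbered 6, 3, 18, 14, 14 and 3. Wnt5a against GFP: miRNAs at least 2-fold higher numbered 0, 0, 2, 13, 1 and 0, and 1 without a filter on dim probes. Wnt5a against GFP: miRNAs at least 2-fold lower numbered 314, 63, 7, 22, 0 and 0. Wnt3a against Wnt5a: miRNAs at least 2-fold higher numbered 467, 502, 27, 24, 9 and 0, 0 also when scaled to the median, scaled to the upper quartile or with cyclic loess, and 1 without normalization between arrays or with scaling on the bright control probes. Wnt3a against Wnt5a: miRNAs at least 2-fold lower numbered 2, 1, 12, 18, 12 and 3. Wnt3a against Wnt4: miRNAs at least 2-fold higher numbered 409, 526, 19, 36, 9 and 0. Wnt3a against Wnt4: miRNAs at least 2-fold lower numbered 5, 2, 18, 21, 19 and 3, and 4 without normalization between arrays. Wnt5a against Wnt4: miRNAs at least 2-fold higher numbered 1, 1, 3, 25, 4 and 0, and 2 without a filter on dim probes or without normalization between arrays. Wnt5a against Wnt4: miRNAs at least 2-fold lower numbered 109, 13, 1, 22, 0 and 0. With the background column 3 miRNAs were 2-fold from GFP in the same direction under all 3 Wnt genes. Wnt4 against GFP: miRNAs detected on only 1 of the 2 arrays numbered 44 with detection at the blank mean plus 5 SD. Wnt3a against GFP: miRNAs detected on only 1 of the 2 arrays numbered 200 with that limit and 106 with the limit from negative control probes. Wnt5a against GFP: miRNAs detected on only 1 of the 2 arrays numbered 52 with the limit at 5 SD.

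The fold rules change the counts by their construction. Plain subtraction left 1105, 976, 1635 and 737 probes above the blank mean on the GFP, Wnt4, Wnt3a and Wnt5a arrays, so that unlike numbers of probes were brought to the same quantiles. The background column follows the signal it is subtracted from. For the other changes of a count or a value given here the cause was not tested.

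The correlation across miRNAs of the log2 differences: Wnt4 and Wnt3a was 0.104 under plain subtraction and 0.327 without a filter. The correlation across miRNAs of the log2 differences: Wnt4 and Wnt5a was 0.537 under plain subtraction and 0.375 with only miRNAs above the median level. The correlation across miRNAs of the log2 differences: Wnt3a and Wnt5a was -0.144 under plain subtraction, the reverse of its sign, and 0.102 with the authors' values, rescaled or not. The number of miRNA lists outside the middle 95% of random lists was 2 for Wnt4 without a filter, 5 with the background column and 1 with the limit from spots without probe. For Wnt5a it was 0 under plain subtraction, and 1 without background correction, with offset 16, with 5 SD, with the background column and with the limit from spots without probe.

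The list median log2 difference: let-7 family, Wnt3a against GFP reversed to 0.29 under plain subtraction, 0.84 with the authors' values and 0.029 with the background column. In the order plain subtraction and authors' table, that of the miR-15/16 family became 0.30 and 0.75, that of the miR-30 family 0.19 and 0.70, and that of osteoblast-regulating miRNAs 0.66 and 1.11, the latter list being at 0.073 with the background column. The X-linked cluster of miR-322 and miR-503 was at 0.29 with the authors' values and 0.067 with the background column. With Wnt5a, osteoblast-regulating miRNAs were at 0.0027 without normalization between arrays, 0.11 with the bright control probes and 0.020 with the rescaled values. The list median log2 difference: Dlk1-Dio3 cluster, Wnt5a against GFP was -1.08 under plain subtraction, -0.38 with the authors' table and -0.0047 without a filter. The median of all miRNAs shifted with Wnt3a by 1.02 under plain subtraction and 1.47 with the authors' table, and with Wnt5a by -1.14 and -0.59. With the background column the log2 difference with Wnt3a became -1.66 for miR-21a-5p, 0.031 for miR-322-3p, 0.15 for miR-503-5p, -0.28 for miR-7036a-5p and -2.30 for miR-711, and with the authors' values 0.038 for miR-322-5p.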

Other observations

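The comparison of arms was chosen after differences of single arms had been seen, and the loci were grouped after the lists had been examined. Grouped by genes within 10000 bp of each other in GRCm38.p6, 17 loci had at least 3 miRNAs detected with both Wnt3a and GFP. Besides the X-linked cluster of miR-322 and miR-503, the lowest medians with Wnt3a were those of Mir30e and Mir30f, at -0.46 (percentile 0.540 of random lists matched on level), and of Mir374b, Mir374c and Mir421 at -0.28 (percentile 4.33), each with all 3 members below 0. The locus of Mir188, Mir362, Mir500, Mir501 and Mir532 had 5 of 6 members below 0 and a median of -0.15 (percentile 2.36). These 3 medians were above 0 in the deposited table and under plain subtraction, where the median of all miRNAs was 1.47 and 1.02. Even the lowest locus, that of miR-322 and miR-503, was above 0 in that table, at 0.11 as grouped here. In the table rescaled on miRNAs listed on all 4 arrays the 3 medians were at -0.69, -0.43 and -0.20. The locus of Mir17, Mir18 and Mir20a had all 4 members above 0 and a median of 0.23 (percentile 96.8). That median was above 0 also under each other scaling and background correction. The upward shifts in the deposited table and under plain subtraction make its sign no check in those settings. It was at 0.21 when scaled to the median and at 0.49 in the rescaled deposited table. The medians of the Mir374b and Mir17 loci lay within the middle 95% of random lists.

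Within the X-linked cluster the arms did not all differ alike: miR-351-5p was at -0.80 and miR-351-3p at -0.08, while the arms of miR-322 were at -1.08 and -1.05. miR-204-5p was at -0.74 and miR-204-3p at 0.23, and miR-708-5p was at -0.97 and miR-708-3p at -0.35. Chosen after its values were seen, the name number also differed: of the 9 miRNAs at least 1.5-fold higher with Wnt3a, 6 had a name number of 6000 or above, against 0 of the 14 lower ones and 36.2% of the 611 detected on both arrays.

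Over 78 pairs of arms detected on both arrays, the differences with Wnt3a of the 5p and 3p arms, which have separate spots, correlated with Pearson's r of 0.72 and Spearman's rho of 0.38, across miRNAs that are not independent replicates. Without the 2 pairs farthest from the median r was 0.35, at percentile 99.94 of 10000 shuffled pairings. With Wnt4 r was 0.02 over 54 pairs, at percentile 56.5, and with Wnt5a it was 0.11 over 49 pairs, at percentile 77.7.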
